A study of Mus musculus with 45 samples.

How the data were processed

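The series holds 45 samples of mice carrying Neurog3Chrono, a reporter of the transcription factor gene Neurog3 read as green and red fluorescence. Of these, 14 are bulk libraries of crypt cells sorted into gate 0 (negative), gate 1 (green), gate 2 (green-red) and gate 3 (red), and 31 are single-cell libraries of reporter-positive cells. The single-cell libraries comprise 16 intestine and 7 organoid libraries made with the 384 primer method and 8 intestine libraries made with the 96 primer method. Both kinds use CEL-seq, which counts the 3' ends of transcripts. The authors' processing notes name BWA 0.6.2-r126 and the mouse build mm10, and the annotation they counted against is not given in the sources used here. Gene positions come from the GENCODE vM21 annotation of GRCm38, matched by symbol.

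The deposited bulk files hold whole-number counts per gene, although their header calls the column normalised. The deposited single-cell files hold estimated counts of transcripts: every value could be turned back into a whole number of distinct molecular barcodes with the correction ln(1-n/K)/ln(1-1/K), with K of 256 for the 96 primer method and 4096 for the 384 primer method and a tolerance of 0.01. A deposited table of cells gives, among other columns, a reporter time, fluorescence scores, the part of the intestine, crypt or villus, the culture condition and a comment per well. Its time has no stated unit, so it is treated as a score by which cells can be ordered.

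Bulk libraries hold between 128073 and 5943013 counts, with 19516 genes and 9 spike-in rows in the files. Intervals and floors cover counting error alone, since the bulk counts carry no molecular identifiers. Genes passing filterByExpr (10878) were tested in edgeR 4.0.16 with TMM scaling, the robust quasi-likelihood test, the gate, and the material code in the descriptions (F03, M01, M02, M03) as a block. Adjusted p values follow Benjamini-Hochberg, two-sided, with a threshold of 0.05. The labels do not say that a code is 1 animal. Before use, the pairing was checked on values centred within gate: libraries of the same code and platform correlated across genes with a median of 0.423 in 19 pairs (0.154 to 0.641), and libraries of different codes on the same platform with a median of 0.387 in 18 pairs, so the block carries mostly the sequencing platform. Libraries from different platforms had a median of -0.407 in 36 pairs. Codes F03 and M01 were sequenced on a NextSeq500 with 75 bp paired ends and codes M02 and M03 on a HiSeq4000 with 150 bp paired ends, and the platform does not vary within a code.

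Single cells were kept when the authors had not marked the well for exclusion and it held at least 1000 transcripts outside spike-ins and mitochondrial genes, which left 4219 of 9600 wells, 4026 of them from the 384 primer method. Leaving out the wells the authors marked was decided after the table of cells was seen, and the alternative with most of them added back is given below. Kept cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (1500 variable genes, 25 components, 15 neighbours, resolution 1.5, seed 0), giving 24 clusters. A cluster was named after a cell type when its 10 highest-ranked genes held 3 markers of that type with at least 20 CPM (counts scaled to a common library total) and a 2-fold excess over other cells. These naming thresholds were settled after the clusters were seen, over 3 versions that moved the names of 2 clusters, and the names end in "-like" for that reason. Values per gene were summed over the cells of a library, rounded, and tested in edgeR as above, with sums of at least 10 cells. The libraries are not tied to animals or cultures in the labels, so p values measure the spread between plates.

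Comparisons along reporter time set the last against the first of 4 quartiles of time, with bounds taken from the intestine cells and the library as a block. Intestine libraries 1a to 1d and 2a to 2d were summed as 1 each. Shares of cell types were compared per library by an exact permutation test over all 245157 splits, and the time of each type by an exact sign-flip permutation test over all sign patterns. Resampling had been planned for the shares and for times over 10 or more libraries, and was replaced by full enumeration after the values were seen. Comparisons of villus with crypt, distal with proximal intestine and organoid conditions, and the profile of genes over all 4 quartiles, were chosen after the table of cells was seen. Tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and DESeq2 1.42.0.

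Gene lists for enteroendocrine cell (EEC) transcription factors, hormones, secretory granule genes, EEC progenitors, enterochromaffin, L, X and D cells, stem, goblet, Paneth, tuft, enterocyte and immune cells, proliferation, Notch and secretory progenitor genes, Wnt targets, cell cycle exit, BMP and Id genes, stress, receptors, ion channels and ribosomal proteins were fixed before the data were examined, as were the main comparisons, the tests and the rule for naming genes. Each list was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over lists and contrasts. Named genes are 11 fixed ones, the 10 largest changes in each direction past the threshold with at least 20 CPM in the higher group and the same sign in every block, and the 4 members of each list with the smallest p. 1 gene that this rule names is not reported here. Other genes are marked as chosen after their values were seen. A fold against a group with no counts is a lower bound from 3 counts over the whole group. Genes with 1 to 3 counts in a group are given as levels without a fold.

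The tests were tried on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. Of the 4-fold changes, 6, 7, 34 and 21 were recovered in the bulk comparisons of gates 1 and 0, 2 and 1, 3 and 2, and 3 and 1, so most changes of that size are missed there. In single cells 89 were recovered between organoid and intestine, 91 along intestine time, 89 along organoid time and 48 in the test of whether time acts differently in the tissues. Recovered genes are called ones with the right direction, and no changed gene was called in the wrong direction. False calls made up 0% to 12.5% of the calls of a comparison, the latter 1 of 8 for gates 2 and 1. Alternatives were DESeq2, upper quartile scaling, other filters, no block, the platform as a covariate, HiSeq4000 libraries alone, other cell minimums, thinned cells, tertiles of time, and each library left out. Among the main comparisons, the 96 primer libraries enter those along time alone, and fluorescence readings and barcode lists were not used here.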

Results

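The bulk data measured gene expression in crypt cells at 4 stages of the Neurog3Chrono reporter, in 3 libraries each of gates 0 and 1 and 4 libraries each of gates 2 and 3. Total counts ran from 1178300 to 4089537 in gate 0, from 128073 to 449462 in gate 1, from 970903 to 5943013 in gate 2 and from 898032 to 3376303 in gate 3, so gate 1 was the shallowest. Single-cell libraries of the 384 primer method held 2636 kept intestine cells (42 to 299 per library, library medians of 1920 to 13912 transcripts per cell) and 1390 kept organoid cells (73 to 309 per library, library medians of 2355 to 13324). The 8 libraries of the 96 primer method held 7 to 41 kept cells each. Organoids are epithelial cultures grown from intestinal stem cells.

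Gate 1 against gate 0 asks what distinguishes crypt cells that have switched Neurog3 on from reporter-negative cells. Neurog3 (chromosome 10, 62133090 to 62134763 on GRCm38), the transcription factor that starts the enteroendocrine programme and drives the reporter, rose from 2.02 ± 1.04 CPM in gate 0 to 2484 ± 2318 CPM in gate 1 (SD, n = 3 each; log2 fold change 9.43, SE 0.74, adjusted p = 4.23e-07). Insm1, a zinc finger repressor of endocrine cells, rose by 8.65 on the log2 scale (adjusted p = 3.04e-07), from 4 counts in all of gate 0 to 279 ± 95.6 CPM. Neurod1 (chromosome 2, 79452521 to 79456751), a factor downstream of Neurog3, rose from 2.43 to 171 ± 258 CPM, a log2 change of 5.34. Sox4 (chromosome 13, 28948919 to 28953713), a factor of early endocrine progenitors, rose by 3.56 (adjusted p = 0.0244), and the granule protein gene Chga (chromosome 12, 102554969 to 102565028) by 3.87 (adjusted p = 0.0199). With HiSeq4000 libraries alone the log2 changes were 10.02 for Neurog3, 3.49 for Neurod1, 4.07 for Sox4 and 1.89 for Chga, the last with an adjusted p of 0.0724. The NextSeq500 platform holds 1 library in each of these gates, too few for a value.

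Of 25 measured EEC transcription factors, 16 rose in gate 1 and 9 did not pass (18 rose when adjusted over the list alone; adjusted p = 0.0834 with an estimated correlation). They included Fev, a factor of serotonin cells, with a log2 change of 6.19, Nkx2-2 with 4.78, and Rfx6, at 58.6 ± 18.9 CPM in gate 1 against 1 count in gate 0. EEC progenitor markers rose in 7 of 11 (8 adjusted over the list alone; adjusted p = 0.081 with an estimated correlation), among them the Notch ligand gene Dll1, with 3.18 on the log2 scale, and Hes6 with 1.72. Pax4, an endocrine lineage factor, stood at 47.4 CPM against 2 counts. Granule genes rose in 8 of 24 (9 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation), led by Chgb with 6.78, and Gfra3, a receptor of the GDNF family, rose by 7.22 to 155 ± 6.42 CPM. Hormone genes rose in 2 of 12 (3 adjusted over the list alone; adjusted p = 0.289 with an estimated correlation), 1 of them Ghrl, the ghrelin gene, with 4.54. X cell markers, the ghrelin cell genes, rose in 3 of 4 (3 adjusted over the list alone; adjusted p = 0.0907 with an estimated correlation), and enterochromaffin markers, those of serotonin cells, rose in 3 of 12 and fell in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.364 with an estimated correlation). Of 8 genes of cell cycle exit, 3 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation): the growth arrest gene Gadd45g rose by 4.42 and the cyclin inhibitor gene Cdkn1c by 2.34, while the cyclin gene Ccnd2 fell by 2.15.

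A part of the markers of other crypt cells was lower in gate 1, and none of 19 enterocyte markers passed (4 lower adjusted over the list alone). Lgr5, the marker of crypt stem cells, fell from 50.8 ± 17.3 CPM in gate 0 to 1.97 ± 3.41 CPM, which is 2 counts, and the tuft cell kinase gene Dclk1 fell from 76.9 ± 33.3 to 4.92 ± 8.52 CPM. Neither passed with HiSeq4000 libraries alone (adjusted p = 0.126 and 0.159) or without the block of material codes (0.0690 and 0.136). Tuft markers fell in 6 of 9 (6, with 1 higher, adjusted over the list alone; adjusted p = 0.289 with an estimated correlation) and stem cell markers in 2 of 9. Itln1, a lectin of Paneth cells, fell by 7.98, and the goblet gene Spink4 fell by 3.26 to 1190.1 ± 249 CPM. Paneth markers fell in 4 of 12 (12 adjusted over the list alone; adjusted p = 0.317 with an estimated correlation) and goblet markers in 2 of 11 (6 adjusted over the list alone; adjusted p = 0.451 with an estimated correlation). Immune cell markers fell in 4 of 10 (8 adjusted over the list alone; adjusted p = 0.142 with an estimated correlation). Srgn, a proteoglycan gene of blood cells, was at least 45.0-fold lower, with no count in gate 1 and 147 ± 80.8 CPM in gate 0, and the tuft channel gene Trpm5 at least 20.6-fold lower. Proliferation genes fell in 3 of 24, among them Rrm2 with -4.42, and Wnt targets in 2 of 11. Of 13 Notch and secretory progenitor genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone), and Atoh1, the factor of the secretory lineage, fell by 4.02. Lyz1 (log2 change -3.98, adjusted p = 0.0684), Muc2 (-2.08), Mki67 (-1.80) and Alpi (-2.11) did not pass, and Olfm4 was below the filter with at most 28 counts in a library. Lyz1 passed with HiSeq4000 libraries alone (-4.02, adjusted p = 0.0364).

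In all, 561 of 10878 genes passed between gates 1 and 0, 187 higher and 374 lower. Upper quartile scaling gave 46.6% higher calls and DESeq2 47.7%, against 33.3% here. Without the block 83 genes passed, and the Neurog3 change was then 9.69 with an adjusted p of 0.0589 and that of Sox4 3.95 with 0.232. Of the lists, 9 EEC transcription factors (adjusted p = 0.0197 with an estimated correlation), 2 progenitor markers (adjusted p = 0.0225 with an estimated correlation), 4 granule genes and 1 X cell marker (adjusted p = 0.0486 with an estimated correlation) were then higher and 1 goblet marker was lower. None of the tuft, Paneth, immune, stem cell, proliferation or Wnt target genes passed, although 6 tuft, 3 Paneth and 5 immune genes were lower adjusted over the list alone, and of the Notch and secretory progenitor genes none was higher and 1 was lower. HiSeq4000 libraries alone gave 34. Counts were 269 without M03 of gate 1, and 223, 341 and 166 without F03, M02 and M03 of gate 0.

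Gate 2 against gate 1 follows the cells as red fluorescence builds up beside green. Neurod1 rose from 171 ± 258 CPM (n = 3) to 3420.5 ± 2548 CPM (n = 4), a log2 change of 4.64 (SE 0.74, adjusted p = 0.00581). Chga rose from 112 ± 108 to 2016 ± 763 CPM, a log2 change of 4.06 (adjusted p = 0.0169). Neurog3 stood at 2612 ± 2873 CPM in gate 2 and its change of 0.70 did not pass (adjusted p = 0.375), nor did that of Sox4 (-0.26) or Mki67 (-0.09). HiSeq4000 libraries alone gave log2 changes of 6.30 for Neurod1, 5.87 for Chga and 0.66 for Neurog3.

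Granule genes rose in 15 of 24 (20, with 1 lower, adjusted over the list alone; adjusted p = 0.169 with an estimated correlation), among them Scgn, a calcium-binding protein gene of endocrine cells, by 4.20. EEC transcription factors rose in 13 of 25 (18 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation), with Isl1, at 3.71, reaching 365 ± 340 CPM, and Myt1 at 3.80. Enterochromaffin markers rose in 8 of 12 (10 adjusted over the list alone; adjusted p = 0.324 with an estimated correlation). Among these, Tac1, the substance P gene, reached 1211 ± 651 CPM (log2 change 3.71) and Tph1, the enzyme that starts serotonin synthesis, 541 ± 330 CPM (3.67). Ion channel genes rose in 4 of 10 (7 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation), among them the calcium channel genes Cacna1a by 2.80 and Cacna2d1 by 4.37. The cyclin inhibitor genes Cdkn1a and Cdkn1c rose by 2.74 and 3.63, with 3 of 8 cell cycle exit genes higher (5, with 1 lower, adjusted over the list alone). Hormone genes rose in 2 of 12 (5 adjusted over the list alone; adjusted p = 0.432 with an estimated correlation), while Cck (3.88, adjusted p = 0.092) and Ghrl (3.92) did not pass. Mapk15, a kinase gene, was at least 19.5-fold higher, with no count in gate 1 and 63.9 ± 39.0 CPM in gate 2, and Wdr7 at least 14.9-fold higher.

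Between gates 1 and 2, enterocyte markers fell in 4 of 19 (4, with 1 higher, adjusted over the list alone; adjusted p = 0.123 with an estimated correlation). Of these, the apolipoprotein genes Apoa1 and Apoa4 fell by 3.03 and 3.15 and the fatty acid binding protein gene Fabp2 by 2.23. Apoc2, a further apolipoprotein gene, fell by 3.74, from 242 ± 203 to 14.4 ± 9.93 CPM. The mitotic genes Bora and Birc5 fell by 5.31 and 3.19, and Birc5 was the 1 of 24 proliferation genes that passed (1 adjusted over the list alone; adjusted p = 0.23 with an estimated correlation). Dll1 fell by 1.84, alone among the 13 Notch and secretory progenitor genes (1, with 1 higher, adjusted over the list alone; adjusted p = 0.378 with an estimated correlation). Agr2, a disulfide isomerase of goblet cells, fell by 2.07, the single goblet marker of 11 to pass (1 adjusted over the list alone; adjusted p = 0.289 with an estimated correlation). Muc2 (-2.05), Lgr5 (1.82), Lyz1 (-0.88), Dclk1 (-0.69) and Alpi (-3.10) did not pass.

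Of 10878 genes, 247 rose and 42 fell between gates 2 and 1. The share of higher calls was 85.5%, against 60.9% with DESeq2 and 70.9% with upper quartile scaling. Without the block 149 genes passed, Neurod1 not among them (4.30, adjusted p = 0.0543), and with HiSeq4000 libraries alone 57. In the fit without the block 6 EEC transcription factors, 5 enterochromaffin markers, 4 hormone genes and 1 cell cycle exit gene were higher, and 1 enterocyte marker and no proliferation, goblet or Notch gene was lower. Granule genes (12 higher, adjusted p = 0.0486 with an estimated correlation) and ion channel genes (3 higher, adjusted p = 0.0477 with an estimated correlation) then passed as lists. Counts were 121, 190, 158 and 105 without F03, M01, M02 and M03 of gate 2, and 642 and 108 without F03 and M03 of gate 1.

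Gate 3 against gate 2 asks what changes once green fluorescence is lost. Neurog3 fell from 2612 ± 2873 to 108.5 ± 116 CPM (SD, n = 4 each; log2 change -4.20, SE 0.47, adjusted p = 3.15e-05), with -4.56 in HiSeq4000 and -3.80 in NextSeq500 libraries alone. Gcg (chromosome 2, 62474530 to 62483650), the glucagon and GLP-1 precursor gene of L cells, rose from 2.17 ± 2.51 CPM (31 counts) to 20569.8 ± 7006 CPM, a log2 change of 13.35 (adjusted p = 3.11e-05), and of 12.54 and 17.42 within the HiSeq4000 and NextSeq500 libraries. Sst, the somatostatin gene, rose from 71.6 ± 131 to 28602 ± 8916 CPM (10.65) and Cck, the cholecystokinin gene, from 655 ± 1039 to 41388 ± 10089 CPM (6.81). Nts, the neurotensin gene, stood at 1216 ± 264 CPM against 1 count in gate 2. Chga (1.51, adjusted p = 0.218), Neurod1 (-0.45) and Sox4 (-1.50) did not pass. In NextSeq500 libraries alone Neurod1 fell by 1.32 (adjusted p = 0.000364) and Chga rose by 1.18 (adjusted p = 0.00154), while HiSeq4000 libraries gave 0.16 and 1.77 without a call. Sox4 was -2.37 in HiSeq4000 and 0.40 in NextSeq500 libraries.

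Hormone genes rose in 8 of 12 in gate 3 (10 adjusted over the list alone), and their call held with an estimated correlation (adjusted p = 0.0301). The same held for L cell markers, 5 of 5 higher (5 adjusted over the list alone), and D cell markers, those of somatostatin cells, 4 of 4 higher (4 adjusted over the list alone), each with an adjusted p of 0.0301. They included Pyy, the peptide YY gene (6.76), Sct, the secretin gene (4.01), Scg2, a secretogranin gene (7.99), and Iapp, the amylin gene (8.10). Granule genes rose in 10 of 24 (17 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation) and enterochromaffin markers in 5 of 12 (6 adjusted over the list alone; adjusted p = 0.238 with an estimated correlation). Afp, an albumin-related secreted protein gene, was at least 1922-fold higher, with 508 ± 159 CPM against no count, Ptger3, a prostaglandin receptor gene, at least 139-fold, and the prohormone convertase gene Pcsk2 at least 114-fold. Receptor genes rose in 5 of 10 (6, with 1 lower, adjusted over the list alone; adjusted p = 0.169 with an estimated correlation). Ion channel genes rose in 3 of 10 (3 adjusted over the list alone; adjusted p = 0.232 with an estimated correlation), among them the potassium channel partners Abcc8 by 3.75 and Kcnj11 by 3.33. Stress genes rose in 5 of 14 (7 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation).

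EEC progenitor markers fell in 5 of 11 (8, with 1 higher, adjusted over the list alone; adjusted p = 0.128 with an estimated correlation), among them Gadd45a by 2.16 and the Notch modifier gene Mfng by 3.39. Tead2, a partner of the Hippo pathway factor Yap, fell by 5.28 and Amotl2, a regulator of that pathway, by 3.47 to 19.1 CPM. Ribosomal protein genes fell in 39 of 78 (60 adjusted over the list alone; adjusted p = 0.128 with an estimated correlation), with a median of -1.08 against 0.06 for all genes. Without the block of material codes 3 of them fell (27 adjusted over the list alone; adjusted p = 0.0455 with an estimated correlation). Markers of other cells moved along. Goblet markers rose in 3 of 11 (6 adjusted over the list alone; adjusted p = 0.345 with an estimated correlation), such as Spink4 by 2.01. Paneth markers rose in 4 of 12 (8 adjusted over the list alone; adjusted p = 0.271 with an estimated correlation), such as Itln1 by 4.16, with 2729 CPM in gate 3 of F03 against 35.9 to 118 CPM in the others. Without gate 3 of F03, 2 of 11 rose, Itln1 by 3.37 (adjusted p = 0.00342). Tuft markers rose in 3 of 9 (6 adjusted over the list alone; adjusted p = 0.283 with an estimated correlation), with Dclk1 at 3.03, which did not pass in HiSeq4000 libraries alone (adjusted p = 0.576). Muc2 (3.54) and Lyz1 (2.55) did not pass, with 4132 ± 4172 and 2095 ± 3846 CPM in gate 3, and neither did Lgr5 (0.14), Alpi (0.71) or Mki67 (0.08). The Muc2 change was 1.00 in HiSeq4000 and 5.04 in NextSeq500 libraries, the latter past the threshold, and it passed without the block (3.88, adjusted p = 0.0480).

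Of 10878 genes, 417 passed between gates 3 and 2, 275 higher and 142 lower. Without the block 118 passed, without Neurog3 (-4.53, adjusted p = 0.255) and Dclk1 (adjusted p = 0.156), with HiSeq4000 libraries alone 25, and with NextSeq500 libraries alone 1472, the last from 4 libraries in these gates and chosen after the data were seen. Lists without the block gave 3 granule genes, 2 enterochromaffin markers, 3 receptor genes (adjusted p = 0.0442 with an estimated correlation), 1 goblet, 1 Paneth and no tuft marker higher, and 1 progenitor marker lower. Counts were 224, 243, 199 and 233 without F03, M01, M02 and M03 of gate 3, 196, 251 and 246 without F03, M01 and M02 of gate 2, and 79 without F03 and M01 of gate 3 together.

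Gate 3 against gate 1 spans the whole reporter-positive path. Chga rose by 5.57 (SE 0.83, adjusted p = 0.00132) and Neurod1 by 4.19 to 1896 ± 376 CPM, while Neurog3 fell by 3.50 (adjusted p = 0.000268). Within HiSeq4000 libraries these changes were 7.64, 6.46 and -3.90. All 12 hormone genes rose (12 adjusted over the list alone; adjusted p = 0.081 with an estimated correlation), as did all 12 enterochromaffin markers (12 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation), 5 of 5 L cell markers (5 adjusted over the list alone; adjusted p = 0.081 with an estimated correlation), 4 of 4 D cell markers (4 adjusted over the list alone; adjusted p = 0.123 with an estimated correlation) and 23 of 24 granule genes (24 adjusted over the list alone; adjusted p = 0.128 with an estimated correlation). Gcg was at least 6282-fold higher and Scg2 at least 416-fold higher, neither with a count in gate 1, and Etv1, a factor of L cells, at least 65.3-fold higher. Gip, the incretin gene of K cells, reached 14376 ± 9858 CPM against 3 counts in gate 1.

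Among EEC transcription factors 14 of 25 rose and 1 fell (16 and 2 adjusted over the list alone; adjusted p = 0.291 with an estimated correlation), with Pax6 at 5.37 and Isl1 at 5.34. Ion channel genes rose in 8 of 10 (9 adjusted over the list alone; adjusted p = 0.128 with an estimated correlation) and stress genes in 10 of 14 (10 adjusted over the list alone; adjusted p = 0.23 with an estimated correlation). Proliferation genes fell in 4 of 24 (8 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation), among them Stmn1, a microtubule regulator gene, by 3.40, while Mki67 (-0.01) did not pass. Ribosomal protein genes fell in 41 of 78 (52 adjusted over the list alone; adjusted p = 0.139 with an estimated correlation), with a median of -1.15 against 0.44 for all genes. Without the block 12 of them fell (36 adjusted over the list alone; adjusted p = 0.0455 with an estimated correlation). Enterocyte markers fell in 4 of 19 (7, with 3 higher, adjusted over the list alone; adjusted p = 0.169 with an estimated correlation). Notch and secretory progenitor genes fell in 3 of 13 (5 adjusted over the list alone; adjusted p = 0.289 with an estimated correlation), with Dll1 at -3.33 and Hes6 at -1.51. In gate 3 the Paneth gene Lyz1 stood at 7865 CPM in F03 and at 159 to 191 CPM in the other libraries.

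In total 1129 genes passed between gates 3 and 1, 859 higher and 270 lower (76.1% higher, against 66.0% with upper quartile scaling). Without the block 605 passed, and the Neurog3 change was then -4.22 with an adjusted p of 0.118 and that of Neurod1 3.38 with 0.0598; HiSeq4000 libraries alone gave 376. Without the block 2 proliferation genes and 1 enterocyte marker were lower. The lists of hormone genes (11 higher, adjusted p = 0.0143 with an estimated correlation), L cell markers (5, 0.0197), granule genes (21, 0.0283), ion channel genes (6, 0.0283) and D cell markers (3, 0.0477) then passed with that correlation. Counts were 522 and 523 without M02 and M03 of gate 3, 679 without M03 of gate 1, and 594 without F03 and M01 of gate 3 together.

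**Figure D1:**
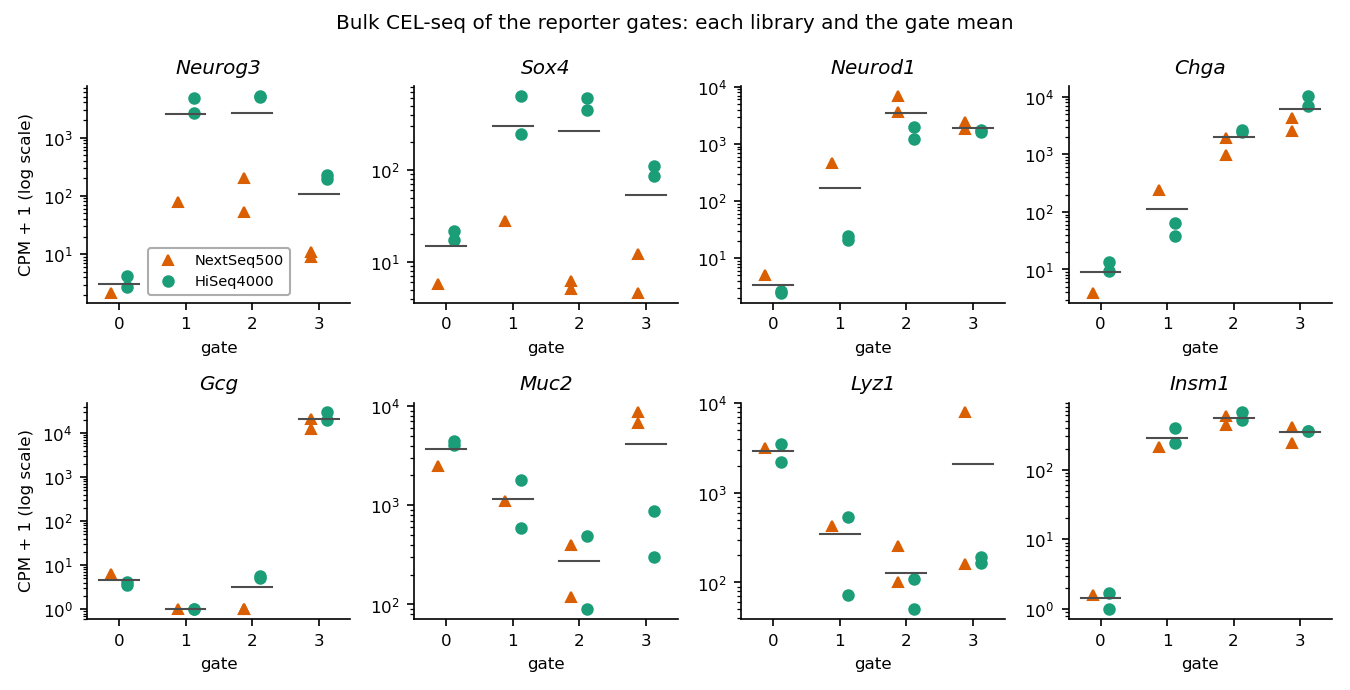
Bulk CPM plus 1, on a log axis, against the gate for Neurog3, Sox4, Neurod1, Chga, Gcg, Muc2, Lyz1 and Insm1; each point is a library, triangles are NextSeq500 and circles HiSeq4000 libraries, and short lines mark gate means. Mean Neurog3 is 2.02 CPM in gate 0, 2484 in gate 1, 2612 in gate 2 and 108.5 in gate 3, and Gcg reaches a mean of 20569.8 CPM in gate 3.

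Single cells placed the same genes on the authors' reporter time. In the intestine the first and the last quartile of time were compared within 10 libraries or library groups (321 and 324 cells). Neurog3 fell from 2807 ± 1009.5 to 100.5 ± 157 CPM (log2 change -5.31, SE 0.42, adjusted p = 3.96e-06) and Sox4 from 1451 ± 830.4 to 149 ± 97.6 CPM (-3.14). Chga rose from 753 ± 355 to 4241 ± 2451 CPM (2.66, adjusted p = 0.000314) and Gip from 320 ± 282 to 35159.8 ± 27616 CPM (6.87). Sct (5.81), Pyy (5.82), Cck (5.37) and Gcg (4.67) rose too, each higher in 10 of 10. Neurod1 (0.43), Mki67 (0.20) and Lyz1 (-0.90) did not pass.

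All 11 measured hormone genes rose along intestine time (11 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), with granule genes higher in 16 of 20 (17 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation) and enterochromaffin markers in 9 of 10 (10 adjusted over the list alone; adjusted p = 0.297 with an estimated correlation). EEC progenitor markers fell in 8 of 10 (9, with 1 higher, adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), including Smarcd2, a chromatin remodelling subunit gene, by 2.81, and Insm1 by 1.86. Tead2 and Amotl2 fell by 4.15 and 3.91. Of 20 EEC transcription factors, 5 rose, such as Pax6 by 3.57, and 9 fell. Ribosomal protein genes fell in 70 of 73 (70 adjusted over the list alone; adjusted p = 0.284 with an estimated correlation). Goblet markers rose in 10 of 11 (10 adjusted over the list alone, adjusted p = 0.332 with an estimated correlation), among them Muc2 by 2.47 and Agr2 by 3.59. Goblet-like cells went from a mean of 2.58% of first-quartile to 14.5% of last-quartile cells, larger in 9 of 10 libraries. The last-quartile share was 59.4% in the group of libraries 2a to 2d and 3.23% to 16% in the others. The rise of goblet markers is not separated from this change in share. Of 6 measured BMP and Id genes, 3 rose (3 adjusted over the list alone), with Id2 at 2.98 and Id3 at 3.30, both targets of BMP signals. In total 2064 of 5074 genes passed, 1048 higher and 1016 lower, and with no filter 3100 passed. The sums along time were not split into crypt and villus cells. Villus cells also had more Sct, Pyy and most BMP and Id genes than crypt cells, and less Neurog3 and most ribosomal protein genes. Location is therefore not separated from time for these genes.

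In organoids, 3 libraries held both ends of time (180 and 274 cells). Their sums were not split by culture condition, and the conditions differed in time. On the 2 sort dates the median times were 6.64 and -8.39 under EEdiffD1, 50.9 and 30.8 under EEdiffD2, and 68.2 and 56.3 under EM. Where a library held several conditions, condition is therefore not separated from time. Neurog3 fell from 2693 ± 559 to 79.6 ± 30.4 CPM (-5.19, SE 0.26, adjusted p = 2.38e-11) and Sox4 by 3.03, while Chga rose by 3.72 and Gip by 7.22. Hormone genes rose in 10 of 11 (11 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), granule genes in 21 of 23 (21 adjusted over the list alone; adjusted p = 0.364 with an estimated correlation) and enterochromaffin markers in 12 of 12 (12 adjusted over the list alone; adjusted p = 0.371 with an estimated correlation). Stem cell markers fell in 8 of 9 (8 adjusted over the list alone; adjusted p = 0.648 with an estimated correlation), with Lgr5 at -1.57, and ribosomal protein genes in 71 of 75 (72 adjusted over the list alone; adjusted p = 0.5264 with an estimated correlation). Receptor genes rose in 7 of 8 and fell in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.373 with an estimated correlation). Galr1, a galanin receptor gene, was at least 38.4-fold higher and Atoh8, a basic helix-loop-helix factor gene, at least 21.2-fold lower. Neurod1 (0.82) passed, and Muc2 (-0.40) and Mki67 (-0.63) did not. In all 2210 of 8756 genes passed, 1183 higher and 1027 lower, with 1128, 1032 and 3566 without organoid libraries 1, 2 and 5, 1375 with DESeq2 and 1464 without the block. The change with time differed between organoid and intestine in 31 of 7968 genes, 14 with a higher and 17 with a lower signed log2 change in organoids, and in 8, 5 and 15 without organoid libraries 1, 2 and 5.

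Profiles over all 4 quartiles, chosen after the data were seen, ordered genes within the intestine (9 libraries with every quartile). Neurog3 was highest in the first quartile in 9 of 9. Its means over the 12 to 15 libraries that held each quartile were 2855, 607, 128 and 85.5 CPM, and the means below rest on the same libraries. Tac1 was highest in the second quartile in 8 of 9 (97.1, 2745, 1810.2 and 509 CPM), as were Fev in 8 of 9 and Rfx3, a ciliary factor gene chosen after its values were seen, in 9 of 9. Tph1 was highest in the third quartile in 7 of 9, and Gip in the last in 8 of 9 (235, 4245, 11846 and 38199.9 CPM). In organoids Gip was highest in the last quartile in 3 of 3, and Sct stayed at or below a mean of 998 CPM, against 12319 CPM in the last quartile of the intestine. Villus cells of the intestine had more Sct than crypt cells, so location is not separated from tissue for this difference. The quartile sums were not split by location either, and villus cells also had less Tac1 and Neurog3.

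**Figure D2:**
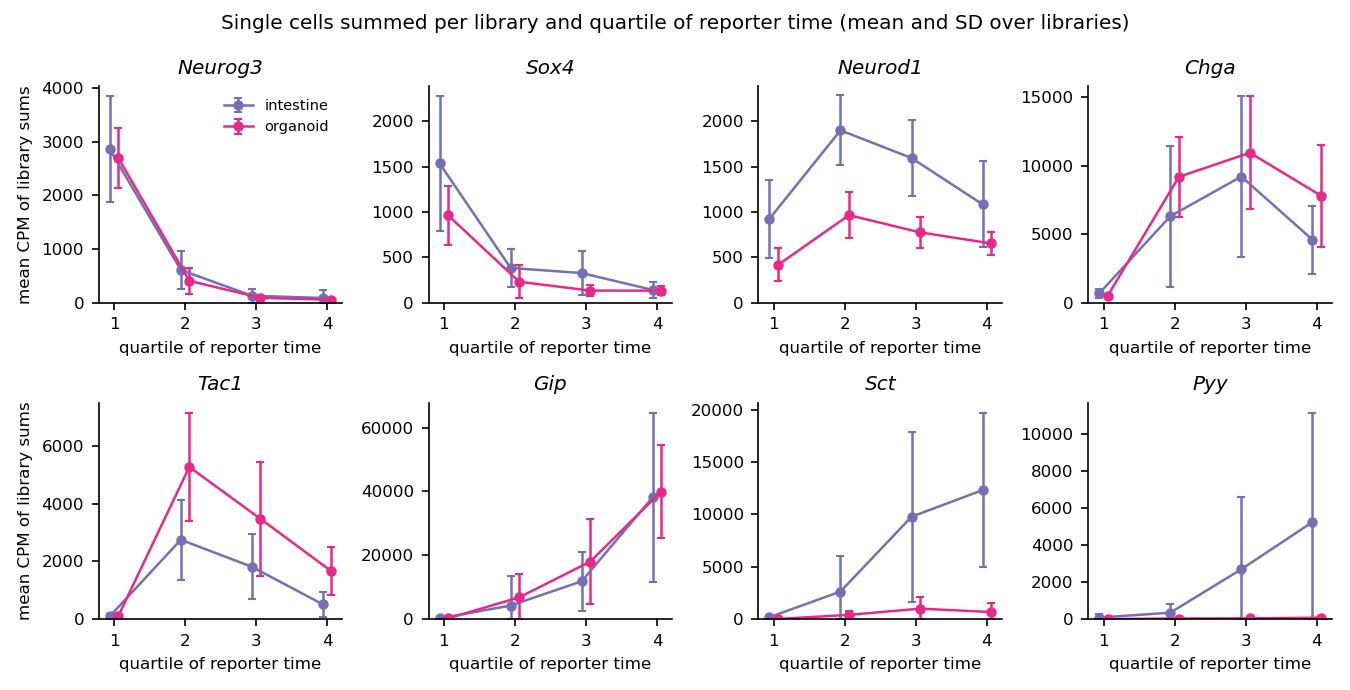
Mean CPM ± SD over libraries against the quartile of reporter time for Neurog3, Sox4, Neurod1, Chga, Tac1, Gip, Sct and Pyy, with 12 to 15 intestine and 3 to 7 organoid libraries at each point; some lower error bars end at 0. Intestine Neurog3 runs from 2855 CPM in the first quartile to 85.5 CPM in the last, and Gip from 235 to 38199.9 CPM.

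Across genes, which are not independent replicates, the bulk changes between gates 3 and 2 and the intestine changes along time had a Pearson r of 0.786 and a Spearman rho of 0.730. Of the genes tested in both, 93 were higher in both comparisons against 20.2 by chance, 115 were lower in both against 23.5, and none had opposite calls. The changes between gates 3 and 1 gave r of 0.576 and rho of 0.459 with intestine time, with 19 opposite calls, and r of 0.577 and rho of 0.505 with organoid time, with 6. Along time, intestine and organoid changes correlated with r of 0.799 and rho of 0.744 over 5049 genes, with 12 opposite calls.

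Of the cell types compared along time, only EEC progenitor-like cells of the intestine passed after adjustment. Neurog3, which drives the reporter, is on the marker list used to name these cells. Their early time was therefore partly set by both definitions and is no independent check of the order. EEC progenitor-like cells were earlier than the other cells of their library in 14 of 14 intestine libraries, by a mean of 60.6 ± 8.37 time units below them (-60.6; exact permutation p = 0.000122, the smallest 14 libraries allow, adjusted 0.00171). They made up 80.5 ± 19.2% of cells in the first quartile and 1.48% in the last. Enterochromaffin-like cells made up 0.0882% in the first quartile and 32.0% in the third. Goblet-like cells were later in 6 of 6 (18.3 units, exact p = 0.0312, adjusted 0.132) and L cell-like cells in 8 of 10 (25.2 units, adjusted exact p = 0.109), so neither passed. In organoids progenitor-like cells were earlier in 4 of 4 (-50.8, exact p = 0.125, the smallest 4 libraries allow).

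Organoid against intestine asks which features of the lineage differ in culture. Every organoid library was sorted on dates with no intestine library, so date and tissue cannot be told apart and no value within a date exists. Organoid libraries also held cells of different culture conditions, which this comparison does not separate. Neurod1 fell in organoid cells from 1427 ± 330 CPM (n = 16) to 727 ± 167 CPM (n = 7), a log2 change of -0.92 (SE 0.19, adjusted p = 0.00229), and Lgr5 rose by 2.92 to 47.9 ± 36.0 CPM. Neurog3 (-0.71), Sox4 (-0.91), Chga (0.69), Lyz1 (-2.69), Mki67 (0.09) and Alpi (-0.14) did not pass. Goblet markers fell in 8 of 11 (11 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), such as Muc2 by 3.24 and Agr2 by 2.44. Paneth markers fell in 3 of 6 and rose in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.259 with an estimated correlation), with the metalloprotease gene Mmp7 at -3.58. Cd74, the chaperone of MHC class II, stood at 2 counts in organoids against 196 ± 211 CPM.

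BMP and Id genes fell in 5 of 8 (5 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation): Id1 (chromosome 2, 152736251 to 152737410) by 5.33 and Id3 (chromosome 4, 136143497 to 136145755) by 6.93, both inhibitors of helix-loop-helix factors, and Smad7, an inhibitor within the pathway, by 2.34. Stress genes fell in 10 of 13 (12, with 1 higher, adjusted over the list alone; adjusted p = 0.259 with an estimated correlation), such as Fos by 3.30. Among hormone genes 1 rose and 2 fell of 12 (2 and 2 adjusted over the list alone): Tac1 rose by 1.22, while Sct fell by 3.38 and Pyy from 2064 ± 2679 to 44.2 CPM (-5.63). The intestine sums hold crypt and villus cells, and villus cells had more Sct and Pyy and less Tac1 than crypt cells. Location is therefore not separated from tissue for Sct, Pyy and Tac1. Chgb rose by 1.46 to 31757 CPM. Scd2, a fatty acid desaturase gene, rose by 3.34, and Egln3, an oxygen-sensing hydroxylase gene, by 4.22. Stem cell markers rose in 3 of 9 (3 adjusted over the list alone). In all 1109 of 10243 genes passed, 555 higher and 554 lower, with 232 when each cell was thinned to 1000 transcripts and 1969 when most wells the authors had marked were added back, an alternative chosen after the data were seen.

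Within EEC progenitor-like cells (3 organoid, 13 intestine libraries) Neurod1 fell by 1.56 and Isl1 by 3.33, and 6 of 19 EEC transcription factors fell (10, with 1 higher, adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), while Neurog3 did not pass (0.49). The tissues lay in different clusters, with 260 of 266 organoid cells in 1 that held no intestine cell and the 687 intestine cells in 2 others. Median times were -8.39 in organoid and -0.285 in intestine cells, so the stage of the cells is not separated from the tissue. Lgr5 rose by 3.03 to 60.1 ± 6.97 CPM, and enterocyte markers rose in 6 of 13 (6, with 2 lower, adjusted over the list alone; adjusted p = 0.259 with an estimated correlation), such as the sucrase gene Sis by 2.13. Cd74 was at least 118-fold lower. Here 663 of 7743 genes passed, and 403 and 385 without organoid libraries 1 and 2.

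Within enterochromaffin-like cells (7 organoid, 14 intestine libraries), the tissues again lay in different clusters: the 429 organoid cells shared 2 clusters with 8 intestine cells, and the other 505 intestine cells lay in 3 clusters without organoid cells. Between these cells Tph1 fell from 4963 to 1878 CPM (log2 change -1.30, adjusted p = 0.000646) and Sct from 5228 to 261 CPM (-4.38), while Ucn3, a urocortin gene, rose by 2.27 and Afp by 3.38. Tph1 and Sct were also higher in villus than in crypt cells of this class, so location is not separated from tissue for them. Of 12 enterochromaffin markers, 5 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.557 with an estimated correlation). The synaptotagmin gene Syt7 fell by 3.81 and Neurod1 by 1.30, and Chga (0.24) did not pass. Goblet markers fell in 6 of 7 (6 adjusted over the list alone; adjusted p = 0.259 with an estimated correlation), with Agr2 at -6.45. Id3 was at least 264-fold lower and Id2 fell by 2.55, with 3 of 4 BMP and Id genes lower (3 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation). The glycolytic gene Pgk1 rose by 2.73. In all 822 of 4074 genes passed.

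**Figure D3:**
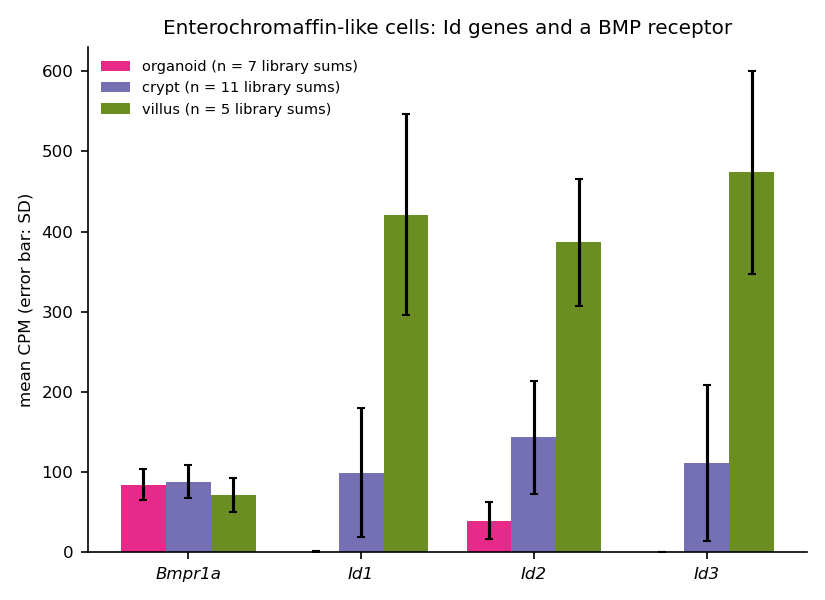
Mean CPM ± SD of Bmpr1a, Id1, Id2 and Id3 in sums of enterochromaffin-like cells from 7 organoid, 11 crypt and 5 villus libraries; bars start at 0 and some lower error bars end at 0. Id1 averages 0.818 CPM in organoid, 99.7 in crypt and 421 in villus sums, while Bmpr1a averages 84.4, 88.3 and 72.0 CPM.

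Other types had fewer libraries. In enterocyte-like cells (3 libraries each) Lgr5 stood at 212.8 ± 100 CPM in organoids against 1 count in the intestine, Smoc2, a stem cell marker, rose by 2.54, and Muc2 fell by 5.86. These cells held a median of 32249 transcripts in organoids and 1674 in the intestine, and 92 of 146 intestine cells lay in a cluster without organoid cells. There 168 of 5160 genes passed, with 87 and 55 without intestine libraries 10 and 11 and 95 and 58 without organoid libraries 1 and 2. In X cell-like cells (4 each) Scd2 rose by 4.40 and the lipase gene Lpl by 4.23, Ghrl (-0.92) did not pass, and 30 of 2815 genes passed. In L cell-like cells (4 organoid, 3 intestine) Ldha, the lactate dehydrogenase gene, rose by 3.15, Scd2 by 3.48 and Chgb by 1.73, and Btg2, an antiproliferative gene, fell by 2.48. Gcg (0.61) and Pyy (-3.66) did not pass there. Of 1292 genes 43 passed; edgeR gave 0 without intestine library 6 (270 of 2150 at an unadjusted p under 0.05), 0 without organoid library 2 (168 of 1092), 169 and 6 without intestine libraries 11 and 7, and 8, 13 and 84 without organoid libraries 1, 6 and 7.

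Shares of cell types did not pass after adjustment. Enterochromaffin-like cells made up 33.5 ± 15.0% of organoid and 16.0 ± 11.6% of intestine cells (n = 7 and 16, adjusted exact p = 0.0606), and D cell-like cells 7.09 ± 4.98% and 3.07 ± 2.53% (0.0727, exact). Paneth-like cells were 0 of 1390 organoid cells, which allows a share of up to 0.216%, against 7.92 ± 10.0% (adjusted exact p = 0.102). Progenitor-like cells made up 14.6 ± 17.8% and 29.3 ± 21.9% (adjusted exact p = 0.225), and 27.6% and 26.6% of cells had no named type. The organoid libraries are not replicates of a single culture condition. Progenitor-like cells ranged from 0% to 74.2% between conditions and sort dates, so organoid means, spreads and tests of shares also reflect which conditions were sorted.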

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

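The tests of the first and the second pattern below, and the tests of cell mix, of clusters and of depth for the third, were chosen only after the result was seen. The test of carry-over in the second pattern replaced 2 earlier ones that decided nothing, and the tests of stage in the first replaced 1, where 9 progenitor markers had a median difference of -0.045 in gate 2 but went both ways (-2.02 to 1.64). The test of clusters in the third was first read on 3 members left by the filter and on the 5 members lower in all cells (-3.51, set by a gene with few counts). The number of splits drawn for the time by tissue test was lowered to 50 after a run with 100.

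The change along reporter time differed between organoid and intestine, by a test of the difference itself, in 31 genes. For the split of these libraries chance can be excluded: of 50 splits the real one alone gave as many (1), and the highest other gave 7. Splits do not separate tissue from sort date or culture condition, and leaving out organoid library 2 gave fewer genes (5) than that other split. Differences are signed, so a change can also be reversed, as for Spdef, which rose by 1.87 in the intestine and fell by 1.23 in organoids. Over all libraries with each quartile, goblet-like cells averaged 2.03% of the first and 14.8 ± 15.1% of the last quartile in the intestine. The latter includes 59.4% in the group of libraries 2a to 2d, which does not enter the test of the difference. In organoids they averaged 1.00% and 3.13%. Differences in goblet genes such as Spdef and Atoh1 are therefore not separated from these shares. Genes with a higher log2 change in organoids were Sgk1 (log2 difference 4.53), a salt- and glucocorticoid-regulated kinase gene, Abca1 (3.09), a cholesterol transporter gene, the calcium channel gene Cacna1h (2.71), Gfra3 (2.61), the apoptosis gene Bok (2.58), Rasal2 (2.52), Mxi1 (2.24), the unfolded protein sensor gene Atf6 (2.22), the sodium channel gene Scn3a (2.01) and Sh3kbp1 (1.99). Genes with a lower one were the Wnt inhibitor gene Wif1 (-6.71), the secretory factor gene Atoh1 (-4.94), Slc6a7 (-3.26), Rab27b (-3.21), the goblet factor gene Spdef (-2.88), Sqrdl (-2.76), Klf4 (-2.70), Tbx3 (-2.64), Car8 (-2.61) and Igfbp4 (-2.54). Without organoid libraries 1, 2 and 5 the count was 8, 5 and 15.

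By list, the median difference was -2.88 for goblet markers (2 of 11 lower, 3 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), -1.60 for BMP and Id genes (3 of 8 lower when adjusted over the list alone; adjusted p = 0.2 with an estimated correlation) and -0.86 for enterocyte markers (adjusted p = 0.709 with an estimated correlation). It was 0.70 for EEC transcription factors (1 of 23 higher, 4 adjusted over the list alone, adjusted p = 0.371 with an estimated correlation), 0.46 for granule genes (adjusted p = 0.646 with an estimated correlation) and 0.46 for enterochromaffin markers (adjusted p = 0.5264 with an estimated correlation). The difference for goblet markers is not separated from the goblet-like shares given above. That for BMP and Id genes is not separated from location. Intestine sums were not split into crypt and villus cells, and most of these genes were higher in villus cells.

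Of 34 groups of values examined for a sample apart from the others, 2 held one, and chance alone sets 1 in 20 groups apart. Lyz1 stood at 7865 CPM in gate 3 of F03, against 159 to 191 CPM in the other gate 3 libraries. Goblet-like cells made up 4.26% of organoid library 3, against 0 to 1.61% in the others. Among wells outside the comparisons, those the authors marked as autofluorescent held 5.49% of their transcripts in Paneth markers, against 0.423% in kept cells, higher in 4 of 4 libraries (exact p = 0.125, the smallest 4 libraries allow). The eGFP row held 4 transcripts in 4 of 9600 wells.

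The first pattern is that Neurog3 and Sox4 were lower in the NextSeq500 than in the HiSeq4000 bulk libraries, by log2 differences of -5.15, -5.46 and -4.38 for Neurog3 and -3.48, -6.38 and -3.67 for Sox4 in gates 1, 2 and 3. A later stage of the NextSeq500 sorts is argued against in gate 2, where the 416 other genes past the threshold between gates 3 and 2 had a median difference of 0.00 (quartiles -0.97 and 0.74) in the direction of that change, whose median size was 3.01, though Neurod1 was higher by 1.86; it stays open in gate 1, with a median of 0.73 (-0.53 and 2.10) of 3.47 and Neurod1 higher by 4.72 in 1 NextSeq500 library, and was not tested in gate 3. A loss of these genes on that instrument is argued against by the single-cell libraries, also run on a NextSeq500, whose first quartile of time averaged 2855 CPM of Neurog3. Reads of some genes assigned differently in the 2 batches may account for it. In gates 1, 2 and 3, 154 genes differed over 8-fold in one direction, 75 lower and 79 higher in NextSeq500 libraries. Between codes M02 and M03 of the HiSeq4000 platform 25 genes did. Among genes chosen after their values were seen, Gapdh averaged 422 CPM in NextSeq500 and 1.02 CPM in HiSeq4000 libraries of gate 2. Rpsa averaged 125 and 5877 CPM there, while Insm1 averaged 504 and 584 CPM. Such differences were thus not limited to endocrine genes. The excess of 154 over 25 is under the 10 times set for it and cannot be told apart from other differences between the batches. No biological explanation beyond stage was tested, and a difference between the animals stays open.

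The second pattern is that Paneth genes were higher in gate 3 of F03 than in the other gate 3 libraries. As a list they were also higher in gate 0 of F03, with a median log2 difference of 5.89 from the HiSeq4000 libraries. Between the platforms this median was 2.85, 1.43 and 5.14 in gates 1, 2 and 3. Lyz1 was not higher there, with 3184 CPM in gate 0 of F03 against 3459 in M02 and 2201 in M03. A difference of F03 in all its gates was not tested as a cause. A difference between the sequencing batches is argued against: Paneth markers had a median log2 difference of 5.37 (-0.999 to 6.73) from gate 3 of M01, sequenced on the same platform. RNA carried over from gate 0 of F03 would bring its abundant transcripts at 1 share, and is argued against by 23 other genes of gate 0, with a median log2 ratio of gate 3 to gate 0 of -2.45 (quartiles -2.91 and -2.17), each below the Paneth median of -0.16 (-1.08 and 0.48), although the Paneth gene Mmp7 (-3.48) lay among the lowest of them. Paneth cells in that sort may be the source, with 9 of 12 markers over 4-fold above M01, and this stays open because Mmp7 (-0.999), Nupr1 (1.32) and Pla2g2a (1.95), also Paneth genes, did not follow the others. The gate selects for red fluorescence, which would remove unlabelled Paneth cells. Paneth-like cells still averaged 7.92 ± 10.0% of kept cells in 16 intestine single-cell libraries, which were sorted as reporter-positive. Wells marked as autofluorescent held 5.49% of their transcripts in Paneth markers, against 0.423% in kept cells, in 4 libraries. The gate is therefore no argument against Paneth cells in that sort.

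The third pattern is that BMP and Id genes were lower in organoid than in intestinal cells. A different mix of cell types is argued against by a median log2 change of -5.12 within enterochromaffin-like cells (-4.66 with genes of 3 or fewer counts at the limit of counting error), and a difference in transcripts per cell by -4.03 with each cell thinned to 1000 (-3.41), although within progenitor-like cells 1 of 5 members, Id1, was lower. Enterochromaffin-like cells of the tissues lie in different clusters, which is argued against as the cause for Id1 and Id3 by 3 other clusters with cells of both, where the 3 members lower within enterochromaffin-like cells had a median of -5.51 without a filter (-4.71 at the limit), Id1 held 4 counts against 211 (adjusted p = 0.00195) and Id3 held 3 counts against 99.0 CPM, while it stays open for Id2 (-0.96), which did not pass there; with the filter, which leaves out Id1 and Id3, the median was -0.19. Villus cells among the intestinal cells are argued against by a median of -4.41 (-3.91 at the limit) between organoid and crypt cells of the enterochromaffin-like class, where Id1 held 2 counts against 99.7 CPM, Id2 was -2.08 and Id3 at least 144-fold lower, while Bmpr1a, a receptor of the pathway, was 0.09. A biological difference between cultured and native cells stays open and was not tested, as does a difference between sort days, since sort date and tissue cannot be told apart here.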

How the results depend on the processing

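The counts without F03 and M01 of gate 3 together, with NextSeq500 libraries alone, with marked wells added back, the comparisons by location and region, and the interaction without each organoid library are tests chosen only after the result was seen. Of the values of single named genes in the bulk comparisons, 1555 kept their side of the threshold, 24 newly passed and 272 no longer passed, and in single cells 2655, 17 and 239; none of the called ones turned in direction, while 34 bulk and 34 single-cell values of genes that did not pass changed sign. Gate 1 had the fewest counts, which may limit the 3 bulk comparisons with it and was not tested. The causes of the changes below were not tested, except that fewer libraries leave fewer degrees of freedom.

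For gates 1 and 0 (561 genes), 83 passed without the block, 34 with HiSeq4000 libraries, 1233 with DESeq2 and 1029 without a filter, and 166 to 821 with 1 library left out. For gates 2 and 1, these were 149, 57, 914 and 722, with 619 for the platform in place of the block and 105 to 642 with 1 left out. For gates 3 and 2 (417), they were 118, 25, 953 and 678, with 1472 for NextSeq500 libraries alone, 79 without F03 and M01 of gate 3, and 196 to 301 with 1 left out. For gates 3 and 1 (1129), they were 605 without the block, 376 with HiSeq4000 libraries, 1868 with DESeq2, 594 without F03 and M01 of gate 3, and 522 to 1213 with 1 left out. Of 92 list tests, 52 passed with the preset and 3 with an estimated correlation, and without the block 53 and 16. Upper quartile scaling, a minimum of 10 CPM and library sizes without the 20 most abundant genes stayed within 1.5 times in every bulk comparison. The median log2 change of all genes was -0.45, 0.37, 0.06 and 0.44 in the order above, and -0.32, 0.15, 0.11 and 0.26 with upper quartile scaling, -0.38, 0.31, 0.06 and 0.36 without the most abundant genes, and -0.20, 0.14, 0.18 and 0.34 with DESeq2.

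For organoid against intestine (1109), 232 passed with thinned cells and 1969 with marked wells added back, and 812 to 1241 with 1 library left out. Along intestine time (2064), 3100 passed without a filter and 1712 to 2119 with 1 left out. Along organoid time (2210), 3566 passed with at least 20 cells per sum, 1375 with DESeq2, 1464 without the block, and 1032 to 3566 with 1 left out. The interaction (31) gave 49 with tertiles of time and 5 to 15 with 1 organoid library left out. With 1 library left out, progenitor-like cells (663) gave 385 to 733, enterocyte-like cells (168) 55 to 198, L cell-like cells (43) 0 to 169, where edgeR's 0 came without intestine library 6 (270 of 2150 at an unadjusted p under 0.05) and without organoid library 2 (168 of 1092), and X cell-like cells (30) 20 to 45. Distal against proximal (271) gave 603 with DESeq2 and 91 without the block, and villus against crypt in enterochromaffin-like cells (1009) gave 522 with DESeq2 and 555 to 1180 with 1 plate left out. Of 216 list tests, 81 passed with the preset and 0 with an estimated correlation. The enterochromaffin-like share, 17.4 percentage points higher in organoids, passed with at least 2000 transcripts per cell (17.7, adjusted exact p = 0.0499) and at least 500 (20.04, adjusted exact p = 0.0316). With means in place of medians, L cell-like cells (26.1 units, adjusted exact p = 0.0273) and enterochromaffin-like cells (17.0 units, adjusted exact p = 0.0047) of the intestine were later. Each type is set against all other cells of its library, progenitor-like ones included, so it is not shown to be later than other mature types. With medians, enterochromaffin-like cells were later in 8 and earlier in 7 libraries. Times of D cell-like and enterocyte-like cells of the intestine with at least 10 cells were not run, and a minimum of 2000 transcripts changes nothing along time, where each timed cell holds more.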

Other observations

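The comparisons of villus with crypt, of distal with proximal intestine and of culture conditions are tests chosen only after the table of cells was seen; the splits were planned, but setting the real one against those that part as many pairs alone was not. Within 10 plates that held both, villus cells had more Sct (23840.7 ± 8586 against 1099 ± 578 CPM, log2 change 4.79, adjusted p = 1.03e-07), Nts (4.97) and Pyy (4.57) than crypt cells, and less Tac1 (249 ± 195 against 1775 ± 1113 CPM, -2.76) and Neurog3 (-3.44). Hormone genes rose in 8 of 12 and fell in 1 (9 and 2 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation). BMP and Id genes rose in 5 of 8 (6 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), such as Id1 by 2.65 and Smad6, an inhibitor in the pathway, by 3.33. Ribosomal protein genes fell in 72 of 74 (73 adjusted over the list alone; adjusted p = 0.259 with an estimated correlation) and proliferation genes in 7 of 10 (7 adjusted over the list alone; adjusted p = 0.464 with an estimated correlation). In all 2134 of 7687 genes passed, and a chance split within these plates can be excluded, as 1 of 100 splits, the real one, gave as many and the highest other gave 692. Within enterochromaffin-like cells of 3 plates the serotonin enzyme gene Tph1 rose by 1.48, Sct by 3.78 and Cartpt, a neuropeptide gene, by 4.99, while Tac1 fell by 3.75 and the vesicular amine transporter gene Slc18a2 by 5.14. There 1009 of 4450 genes passed, with 555 and 587 without plates 11 and 13 and 522 with DESeq2; the 4 splits that part as many pairs (1 as large, highest other 0) are too few for a share under 0.05.

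Distal cells, compared with proximal ones within 11 plates, had less Onecut2, a homeobox factor gene (104 ± 172 against 764.5 ± 228 CPM, log2 change -3.53, adjusted p = 0.000655), and less Gata4, a factor of the proximal intestine (39.4 ± 22.4 against 121 ± 42.4 CPM, -1.55). Sox4 fell by 1.46, and EEC progenitor markers fell in 4 of 10 (8 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation). Krt20, a keratin gene, rose by 2.21, Etv1 by 2.04 and B4galnt2, a glycosyltransferase gene, by 1.46. L cell markers rose in 1 of 4 (2 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation), while Pyy (3.10, adjusted p = 0.0774) and Gip (-2.61, adjusted p = 0.153) did not pass. In all 271 of 5934 genes passed, with 603 in DESeq2 and 91 without the plate block. A chance split within these plates can be excluded, as 1 of 100 splits, the real one, gave as many and the highest other gave 5.

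In organoids, progenitor-like cells made up 40.9% and 74.2% of the cells of the 2 sort dates under the condition named EEdiffD1 and 0% and 2.74% under EEdiffD4, while enterochromaffin-like cells went from 11.9% and 5.47% to 56.0% and 27.4%. Times lay within 1 unit of the lowest value in 171 of 2281 timed intestine cells (7.50%) and 212 of 1182 organoid cells (17.9%). Wells the authors marked as doublets held a mean of 49028 transcripts, against 7796 in kept intestine cells.

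Among other splits of the libraries, the real split was the 1 that gave as many genes in each comparison. Where a block pairs the libraries, it was set against the splits that part as many pairs. These are 4 for gates 1 and 0 (561 genes, highest other 3) and organoid time (2210, highest other 0), and 8 each for gates 2 and 1 (247 higher and 42 lower, highest other 1), gates 3 and 2 (417, highest other 0) and gates 3 and 1 (1129, highest other 178). They are too few for a share under 0.05, as are the 10 splits of enterocyte-like cells (168, highest other 0). Splits that part fewer pairs, with both libraries of a code on 1 side, gave at most 4, 2, 4 and 18 genes in the bulk comparisons in the order above, and 0 along organoid time. A chance split of the libraries can be excluded for organoid against intestine (1109, highest other 341 of 100 splits), intestine time (2064, highest other 954 of 100), progenitor-like cells (663, highest other 40 of 100), enterochromaffin-like cells (822, highest other 255 of 100) and X cell-like cells (30, highest other 7 of 35). The libraries are not tied to animals or cultures, and the organoid ones came from 2 sort dates. Splits therefore do not exclude chance between animals, cultures or dates. For L cell-like cells the real split gave the most genes (43, highest other 32 of 35). Leaving out some single libraries left no gene past the threshold there, so chance is not excluded for them.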
